A study of Mus musculus with 4 samples.

How the data were processed

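Droplet-based single-cell RNA sequencing with the 10x Genomics 3' chemistry was applied to splenic B cells of 3-month-old female mice. The 4 libraries fall into 2 genotypes named in their titles: FcgRIIB-/- (libraries 1 and 2) and FcgRIIB-/-IRF7-/- (libraries 1 and 2), called single-knockout and double-knockout hereafter. Per the labels' protocols, live CD3-negative B220+ CD19+ cells were sorted from each animal as IgD-negative and IgD-positive fractions, and the fractions were recombined so that 90% of the cells were IgD-negative and 10% IgD-positive. Each library was taken as 1 animal on the strength of that protocol. Dates and batches of library preparation are not given in the sources used here, so a batch and the genotype cannot be told apart. The kit version in the labels was not used in any calculation. IRF7 ChIP-seq libraries named in the design text were not analysed here.

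The deposited matrices hold raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger 6.0.0 per the file headers. Per the submitters' processing notes, the genome build was mm10, and Seurat 4.99 was also named, without a role. The gene annotation release behind the counts is not given in the sources used here. No deposited barcode had fewer than 500 UMIs, so the files hold barcodes already called as cells. The 32285 gene IDs were matched by ID to the GENCODE annotation of mm10, which gave a position for 99.61% of them, and all coordinates are 1-based mm10 positions of whole genes. A symbol shared by several IDs was reported by its ID.

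Cells were kept with at least 300 detected genes and at most 10% of UMIs from mitochondrial genes. Doublets were then treated with Scrublet, run per library in scanpy 1.11.5. Its automatic threshold marked 0, 343, 4 and 2 cells, which did not work in 3 of the libraries, so the cells with the highest scores were removed at a fixed rate of 0.8% per 1000 cells. This removed 941 and 975 cells of the single-knockout and 471 and 268 of the double-knockout libraries. Of 36842 barcodes, 31252 were kept. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours went into Leiden clustering (igraph 0.11.9) at resolution 1 without batch integration. Irf7, Fcgr2b, immunoglobulin, T cell receptor, mitochondrial and ribosomal genes and the interferon-stimulated list were left out of the clustering. The 18 clusters were named from fixed marker lists. A name ending in "-like" means a match to markers only, and 4 clusters without a name of their own (4, 8, 9 and 11) were compared by number. A hemoglobin-led cluster of 1008 cells, 918 of them from single-knockout library 1, and an NK cell cluster of 23 cells were left out, as were 3 small unnamed clusters from the comparisons within classes. The 30221 B cells comprised 8447, 9584, 6880 and 5310 cells per library.

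UMI counts were summed per library over all B cells and over each class, because the library and not the cell is the replicate. Sums were tested with edgeR 4.0.16 (R 4.3.3) using TMM normalization, filterByExpr and the quasi-likelihood test, with Benjamini-Hochberg adjustment and a call at an adjusted p under 0.05. Adjusted p values for single genes come from this test unless another tool is named. Fold changes are double-knockout over single-knockout on the log2 scale, with standard errors, and CPM are edgeR counts per class sum on its usual scale. A class was tested with at least 20 cells in every library. The difference between the genotype effects in germinal center-like and follicular-like cells was an interaction term with the library as a block. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation, and fry was run beside them. The estimated correlation rests on 2 libraries per group, called no list in any comparison and was not tried on simulated data. A call lost with it is therefore no evidence against a list. Within classes, the adjustment ran over lists and classes together. Shares of cells carry exact (Clopper-Pearson) 95% intervals, which cover counting error only, with an exact two-sided permutation test of the libraries, whose smallest possible p is 0.3333. Cell counts per class were also tested with edgeR, which pools the spread over classes. Isotype shares are shares of all heavy chain constant region UMIs.

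The 26 gene lists, the markers, the filters, the tests and most of the alternatives were fixed before the data were examined. Genes were named by a rule fixed at the same time. It took Irf7 and Fcgr2b first. It then took, among genes past the threshold with non-overlapping libraries and a mean of at least 10 CPM, the 10 largest rises and 10 largest falls. From each list with a call, or with at least 3 members past the test, it took up to 4 members with the smallest p. Only part of the genes the rule allows are printed. Genes named outside it, in the closing section, were chosen after their values were seen.

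The fits were tested on simulated data drawn from the real means, dispersions and library sizes with known fold changes. In all B cells the test called 61% of genes changed 2-fold and 88.8% of those changed 4-fold, and 16 of 12895 unchanged genes. In the plasma cell-like class it called 4.12% and 67.0%, and for the interaction 30.1% and 69.3%. In follicular-like cells, the only class in which lists were simulated, none of 39 unchanged lists was called. Those lists were random and their genes were simulated independently. The preset correlation was therefore not tested on lists whose members move together. Replicate libraries were compared by a chi-square test of their summed counts, which gave 20.7 per degree of freedom in the single-knockout and 60.2 in the double-knockout group, a measure that sets separate animals against counting noise alone.

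Alternatives covered normalization (RLE), DESeq2 1.42.0, no count filter, a replicate block, each library left out, immunoglobulin genes left out, doublets kept, a filter of 500 genes and 5% mitochondrial UMIs, Leiden resolutions 0.5 and 2, all kept cells, equal class makeup (limma), the same limma fit without the weighting, an estimated correlation and clustering without called genes. In the free-RNA alternative, a share of each library's own profile, sized on germinal center markers (follicular markers for the germinal center classes), was subtracted from the class sums. All of these markers are also members of the germinal center or the follicular and quiescence list, so the subtraction draws those lists toward no difference by construction. Single markers gave unlike shares, from 2.93% to 129% in germinal center-like cells of single-knockout library 1. Another alternative drew equal numbers of cells and UMIs per library. Python 3.11.15, anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.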

Results

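FcgRIIB is the inhibitory Fc receptor for IgG on B cells, and mice without it develop lupus-like autoimmunity. IRF7 is a transcription factor that is itself induced by interferon and drives type I interferon responses. The libraries ask how B cells of FcgRIIB-deficient mice differ when IRF7 is also absent, with attention to germinal center and plasma cell differentiation. The deposited matrices held 63686963 and 81008885 UMIs in the single-knockout libraries and 39374044 and 27026889 in the double-knockout libraries. The kept cells had medians of 4406 and 5566 UMIs in the single-knockout and 3825 and 3767 in the double-knockout libraries. Within each of the 10 classes and clusters tested the double-knockout cells were the deeper ones. In follicular-like cells the medians were 2267 and 2506.5 UMIs in the single-knockout and 3492 and 3758 in the double-knockout libraries. The median mitochondrial share was 3.17% and 2.65% in the single-knockout and 3.69% and 5.30% in the double-knockout libraries. All comparisons rest on 2 libraries per group.

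The deleted genes were read first. Irf7 (ENSMUSG00000025498, chromosome 7, 141262706 to 141266481) was at 18.2 and 20.9 CPM over all kept single-knockout cells and at 0.843 and 0.888 CPM in the double-knockout libraries, from 997, 1409, 30 and 22 UMIs. The log2 fold change was -4.68 (SE 0.16, edgeR quasi-likelihood adjusted p = 8.3e-05). Among the 10 classes and clusters tested, Irf7 passed the test in 9. It had 0 UMIs in both double-knockout libraries in follicular-like cells and in cluster 4, which put it at least 27.1-fold and at least 34.7-fold lower there against a floor of 3 counts over the group. Fcgr2b (ENSMUSG00000026656, chromosome 1, 170958617 to 170976547) is deleted in both groups. It was at 10.96 and 10.4 CPM in single-knockout and 44.6 and 45.3 CPM in double-knockout libraries. The rise was 1.89 on the log2 scale (SE 0.09, edgeR quasi-likelihood adjusted p = 9.2e-05). Classes differed in this. Within marginal zone-like cells its level was 68.5 and 69.4 CPM against 71.4 and 70.6 CPM, and in cluster 4 40.3 and 49.3 CPM against 37.3 and 39.8 CPM. In germinal center-like cells it was 1.31 and 3.01 CPM against 9.02 and 14.4 CPM, from 10, 26, 5 and 9 UMIs. In dividing germinal center-like cells it was 1.58 and 1.46 CPM against 7.97 and 4.05 CPM. A 3' tag can lie outside the deleted part of a gene, so the remaining Fcgr2b counts check nothing about the deletion.

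Germinal center B cells, the rapidly dividing cells that mutate and select their antigen receptors, made up most of the single-knockout cells and few of the double-knockout cells. They comprised a class of 3 clusters named dividing and a germinal center-like class led by Aicda, Rgs13 and S1pr2, in which 39.4% and 37.4% of single-knockout and 42.3% and 28.0% of double-knockout cells also carried 5 or more UMIs of the proliferating markers. Their joint share of B cells was 56.4% (95% interval 55.4 to 57.5) and 56.6% (55.6 to 57.6) in the single-knockout libraries and 3.47% (3.05 to 3.93) and 3.58% (3.09 to 4.11) in the double-knockout libraries, a difference of -53.0 percentage points. Transitional-like cells, named after immature B cells newly arrived from the marrow, took the opposite course at 1.81% and 2.24% against 30.3% and 46.0%. The name is weakly held. A cluster of 4758 cells had 1 transitional (Vpreb3), 1 follicular (Klf2) and 1 atypical marker (Zeb2) among its 10 leading genes. Another of 139 cells had 2 transitional markers (Sox4 and Myb) and 1 T cell marker (Il7r). These are shares of a sorted mix of 90% IgD-negative and 10% IgD-positive cells and not of the spleen. The exact permutation p was 0.3333 for both, the smallest that 2 against 2 libraries can give. The edgeR test on cell counts called 6 of the 11 groups of cells. The log2 fold change was -4.15 (SE 0.54, adjusted p = 6.1e-07) for dividing germinal center-like, -3.70 (SE 0.53, adjusted p = 2.1e-06) for germinal center-like and 4.23 (SE 0.54, adjusted p = 6.1e-07) for transitional-like cells.

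Cluster 9, led by Ccnd2, Nfkbid and Egr3, rose from 1.87% and 2.71% to 10.97% and 10.4% (log2 fold change 2.22, edgeR adjusted p = 0.000421). Cluster 11, led by Gm8369, Plac8 and Myb with follicular markers behind them, rose from 1.29% and 1.51% to 9.56% and 10.8% (log2 fold change 2.86, edgeR adjusted p = 3.5e-05). Plasma cell-like cells, which secrete antibody, fell from 1.89% and 2.81% to 1.15% and 0.395% (log2 fold change -1.59, edgeR adjusted p = 0.00867). The plasma cell call was lost without either single-knockout library, at Leiden resolution 0.5, with the stricter cell filter and when called genes were left out of the clustering, and the cluster 9 call was lost without single-knockout library 1. Marginal zone-like cells stood at 6.65% and 5.42% against 13.6% and 5.08%, follicular-like cells at 6.03% and 3.82% against 4.56% and 8.15%, and cluster 4 at 10.5% and 7.16% against 12.95% and 5.22%. In each of these classes the libraries of the genotypes overlapped, and none passed the test. Cluster 8, led by Ly6d, Wfdc21 and Klf2, was at 12.4% and 16.6% against 12.2% and 9.81%, and together with transitional-like cells, with which it shared leading genes, at 14.2% and 18.9% against 42.5% and 55.8%.

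Shares of a whole move together, so they were also taken among the cells outside the germinal center classes. There transitional-like cells were at 4.16% and 5.17% against 31.4% and 47.7% (log2 fold change 3.08, edgeR adjusted p = 0.000278) and plasma cell-like cells at 4.35% and 6.46% against 1.19% and 0.410% (log2 fold change -2.74, edgeR adjusted p = 0.000585). Cluster 8 was then lower, at 28.5% and 38.3% against 12.6% and 10.2% (log2 fold change -1.55, edgeR adjusted p = 0.0196), and cluster 9 no longer passed (adjusted p = 0.0717). Cluster 8 and transitional-like cells together were at 32.7% and 43.4% against 44.1% and 57.9% of these cells, a difference of 12.9 points beside 34.9 for transitional-like cells alone. Genes that define the classes also differed between genotypes, so the cells were clustered again without them. Without the genes called within any class, the germinal center share was 57.4% and 56.6% against 3.48% and 3.62%, and the transitional-like share, which then took in cluster 11, was 4.58% and 6.16% against 45.1% and 59.0%. Without all genes called over all B cells, the germinal center share was 53.0% and 56.6% against 17.6% and 16.4%, the plasma cell-like share was 2.44% and 3.60% against 3.09% and 1.79%, and 2 calls were left.

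**Figure D1:**
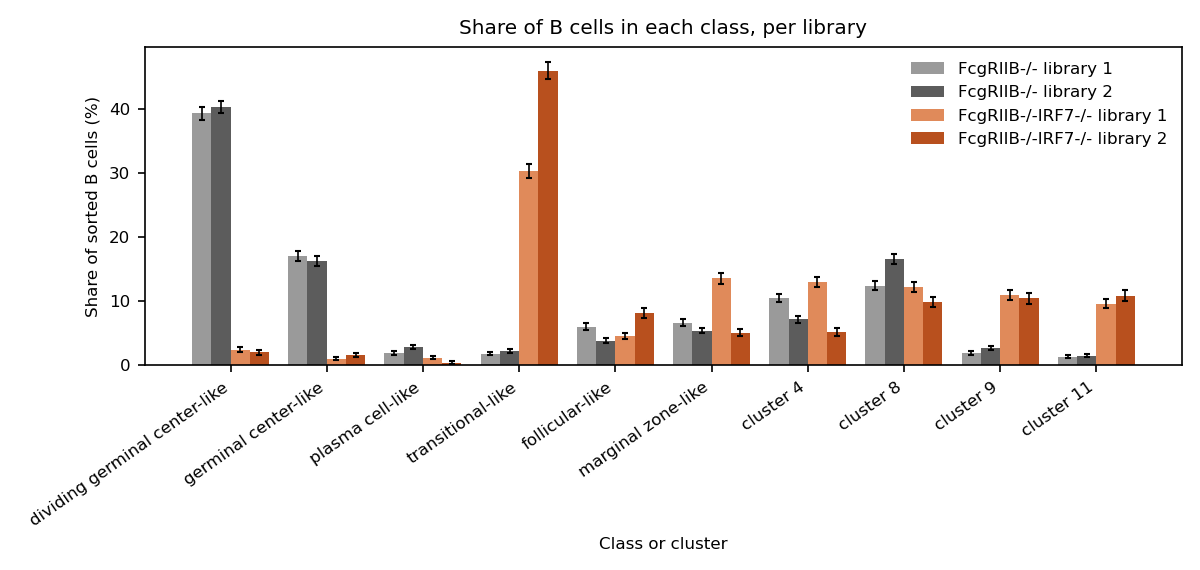
Share of B cells in each class or cluster (vertical axis, percent of B cells) for each of the 4 libraries, with exact 95% intervals that cover counting error only. Dividing germinal center-like cells are at 39.4% and 40.3% in the single-knockout and 2.44% and 2.03% in the double-knockout libraries, and transitional-like cells at 1.81% and 2.24% against 30.3% and 46.0%.

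Summed over all B cells, genes of germinal center and dividing cells were lower and genes of resting B cells higher in double-knockout libraries. Of 13324 genes tested, 7592 passed, 3694 higher and 3898 lower. Leaving out single-knockout library 2 gave 4688 calls. With every class weighted to the same share in each library, limma called 146 genes, 45 higher and 101 lower, of which 124 were among the 7592. The same limma fit without the weighting called 7830, 4810 higher and 3020 lower, of which 6649 were among the 7592, so the lower number came with the weighting and not with the tool, while the balance of rises and falls differed between the tools. Germinal center classes held 76.3% and 75.8% of B cell UMIs in the single-knockout and 9.68% and 8.51% in the double-knockout libraries.

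The germinal center list had 17 of 22 measured members lower, 3 higher and 2 not called (median log2 fold change -2.28, camera adjusted p = 2.3e-05), and the same numbers adjusted over the list alone. With an estimated correlation this list and the dark zone and cell cycle lists lost their calls (adjusted p = 0.517 with an estimated correlation for each). Among the falls, Gcsam (ENSMUSG00000022659, chromosome 16, 45610380 to 45622867), a signalling adaptor of germinal center cells, went from 228 and 233 CPM to 16.3 and 16.6 CPM (log2 fold change -3.99, SE 0.09). Mef2b (ENSMUSG00000079033, chromosome 8, 70139711 to 70167488), a transcription factor upstream of Bcl6, went from 350 and 334 CPM to 35.2 and 34.2 CPM. Aicda (ENSMUSG00000040627, chromosome 6, 122553801 to 122564180), the deaminase of somatic hypermutation and class switching, went from 211 and 241 CPM to 31.4 and 26.8 CPM. S1pr2, which retains cells in the germinal center, changed by -3.29 and Nuggc by -3.57. At equal class makeup Gcsam, Mef2b and Nuggc still passed, and Aicda (-0.38) and S1pr2 (-0.26) did not. The dark zone list had 12 of 15 members lower and 3 not called (median -2.92, camera adjusted p = 4.1e-05; 12 lower adjusted over the list alone). All 36 cell cycle members were lower, also adjusted over the list alone (median -2.73, camera adjusted p = 9.7e-15), including the mitotic genes Cenpe at -2.94, Cdc20 at -2.85, Kif11 at -2.66 and Aurkb at -2.19, and none of these 4 passed at equal class makeup.

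Lists of metabolism moved the same way. Oxidative phosphorylation had 36 of 37 members lower and 1 not called (median -0.87, camera adjusted p = 7.2e-10; 36 lower adjusted over the list alone), and Myc and glycolysis had 16 of 21 lower, 2 higher and 3 not called (median -0.75, camera adjusted p = 0.000517; 17 lower and 2 higher adjusted over the list alone). The ATP synthase subunit Atp5b went from 533 and 528 CPM to 304 and 301 CPM, and the glycolytic enzyme Gapdh from 1632 and 1763 CPM to 571 and 431 CPM, and neither passed at equal class makeup. With an estimated correlation neither list kept its call (adjusted p = 0.517 and 0.558 with an estimated correlation).

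Genes of resting and recirculating B cells rose. The follicular and quiescence list had 16 of 19 members higher and 3 not called (median 1.53, camera adjusted p = 2.1e-06; 16 higher adjusted over the list alone). S1pr1 (ENSMUSG00000045092, chromosome 3, 115710433 to 115715072), the receptor for egress into blood, rose from 53.8 and 53.8 CPM to 301 and 298 CPM (log2 fold change 2.29, SE 0.08, edgeR adjusted p = 8.3e-05). Klf2 (ENSMUSG00000055148, chromosome 8, 72319033 to 72321656), a transcription factor of quiescence, rose from 180 and 190 CPM to 876 and 1020 CPM. The marginal zone list had 14 of 17 higher, 2 lower and 1 not called (median 1.54, camera adjusted p = 0.000354), with Hes1 at 2.38 and Cd36 at 2.33. The memory list had 11 of 15 higher, 2 lower and 2 not called (median 1.34, camera adjusted p = 0.00336), with Hhex at 2.26, and the B1 list 7 of 14 higher and 7 not called (median 0.58, camera adjusted p = 0.0232), with Rnf130 at 1.47. These 3 counts were the same adjusted over the list alone. The largest rises over all genes included Gm47730 at 3.87, Wfdc21 at 3.39 and Sox4, a transcription factor of immature B cells, at 3.04, and the largest falls Rflna at -4.53, Emp2 at -4.35 and Tox2 at -4.33. Wfdc21, Klf2, Hes1 and Sox4 were among the leading genes of transitional-like clusters, so part of these rises goes with the rise of that class. At equal class makeup Sox4 was at -0.05 and Klf2 at 0.20 without a call, while Wfdc21 (0.93) and Hes1 (0.57) still passed, and within classes Hes1 was called higher in 7 of 10 and Wfdc21 in 5 of 7. The B1 call was lost without double-knockout library 1 (camera adjusted p = 0.118), and all 4 calls with an estimated correlation (adjusted p = 0.517 to 0.628 with an estimated correlation).

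Signalling lists showed mixed members. B cell receptor signalling had 18 of 29 members higher, 2 lower and 9 not called (median 0.40, camera adjusted p = 0.00561), with the adaptor Bank1 at 1.42 and the kinase Lyn at 1.03. NF-kB targets had 13 of 24 higher, 4 lower and 7 not called (median 0.39, camera adjusted p = 0.0379), with Nfkbid at 1.83, and nucleic acid sensing and interferon signalling 16 of 28 higher, 3 lower and 9 not called (median 0.53, camera adjusted p = 0.0110), with the receptor chain Ifnar1 at 1.47 and the feedback inhibitor Socs1 lower at -2.06. The interferon-stimulated list had 27 of 42 lower, 8 higher and 7 not called (median -0.85, camera adjusted p = 0.00128; 29 lower and 8 higher adjusted over the list alone). Ifi27l2a (ENSMUSG00000079017, chromosome 12, 103442167 to 103443680) fell from 693 and 656 CPM to 151 and 146 CPM, and the sensor Zbp1 fell by 1.30 on the log2 scale. The cytosolic RNA sensor Ddx58, at 1.71, and Samd9l, at 74.1 and 70.1 CPM against 204 and 260 CPM, were higher, and turned to -0.28 and -0.06 at equal class makeup, without a call. The other 3 list counts were the same adjusted over the list alone. The NF-kB call was lost without single-knockout library 1 (camera adjusted p = 0.0714), single-knockout library 2 (0.0703) or double-knockout library 1 (0.0807), and all 4 lists lost their call with an estimated correlation (adjusted p = 0.517 with an estimated correlation).

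Another 12 lists were not called over all B cells by camera. The fry test called 14 lists there, which included apoptosis and survival (lower) and the genes near Fcgr2b (higher) among these 12 (fry adjusted p = 0.00926 for both) and left out the B1 list (0.0788). Members higher, lower and not called numbered 9, 7 and 4 for light zone and activation, 4, 5 and 14 for plasma cell, 3, 13 and 16 for endoplasmic reticulum folding and secretion, 1, 3 and 7 for MHC class II, and 3, 10 and 6 for MHC class I. They numbered 8, 9 and 4 for atypical or age-associated B cell, 12, 7 and 7 for immediate early and dissociation, 5, 9 and 5 for apoptosis and survival, 6, 4 and 3 for cytokines and chemokines, and 0, 3 and 3 for class-switched immunoglobulin. Genes near Irf7 on chromosome 7 numbered 10, 10 and 15, with Hras at -1.44, and genes near Fcgr2b on chromosome 1 numbered 16, 7 and 16, with Mndal at 1.78, which turned to -0.23 without a call at equal class makeup. The unswitched immunoglobulin list had both of its 2 members higher and was too small to test. Without double-knockout library 1 the plasma cell, endoplasmic reticulum, MHC class I and class-switched lists passed (camera adjusted p = 0.0209, 0.00718, 0.0215 and 0.0112), all lower. The endoplasmic reticulum list also passed without single-knockout library 1 (0.0382), and the class-switched list without single-knockout library 1 (0.0224) or 2 (0.0424).

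Class-switched heavy chain RNA made up a smaller part of the double-knockout heavy chain RNA. Switched constant regions (IgG, IgA and IgE) held 56.6% and 73.0% of heavy chain constant region UMIs in single-knockout and 25.3% and 6.50% in double-knockout B cells, a difference of -48.9 percentage points. IgM from Ighm (ENSMUSG00000076617, chromosome 12, 113418558 to 113422730) held 42.4% and 26.3% against 72.6% and 89.7%. IgG2c from Ighg2c (ENSMUSG00000076612, chromosome 12, 113285325 to 113288932) held 15.2% and 20.98% against 2.27% and 1.07%. IgG1 held 8.77% and 13.01% against 0.778% and 1.25%, and IgE 0.0910% and 0.0944% against 0.00441% and 0.00353%. The edgeR test over all B cells gave log2 fold changes of -2.93 for Ighg1 (SE 0.33, adjusted p = 0.000776), -2.89 for Ighg2c (SE 0.45, adjusted p = 0.00262) and -3.95 for Ighe (SE 0.31, adjusted p = 0.000246), while Ighg3 was at 3.02% and 14.8% against 6.72% and 0.381%. The exact permutation p was 0.3333 for the switched share, the smallest possible. Plasma cells carry much of this RNA, and without them the switched share was 41.2% and 47.6% against 7.66% and 4.03%.

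Within dividing germinal center-like cells the switched share was 62.6% and 71.5% against 15.3% and 29.5%, and within germinal center-like cells 63.4% and 64.8% against 10.6% and 50%. Within plasma cell-like cells it was 68.0% and 87.5% against 49.7% and 23.02%, and within follicular-like cells 11.4% and 10.4% against 10.4% and 3.82%. In cluster 4, led by S100a6, Gimap4, Ahnak and Ccr6, it was 44.7% and 57.9% against 45.9% and 67.4%, with no separation of the genotypes. The class-switched list had 0 to 4 members called lower per class and fell in 8 of the 10 classes and clusters by camera, all but cluster 4 and germinal center-like cells. With an estimated correlation it fell in none (adjusted p = 0.514 to 0.704 with an estimated correlation). After free RNA was subtracted it no longer passed in dividing germinal center-like (camera adjusted p = 0.269) or follicular-like cells (0.127, with a median of -0.52 against -0.69 before) and turned to a median of 0.02 in marginal zone-like cells (0.859), while in transitional-like cells and clusters 8, 9 and 11 too few members were left to test. The call was also lost in follicular-like cells without single-knockout library 1 (0.0736) or double-knockout library 2 (0.318), in dividing germinal center-like cells without double-knockout library 1 (0.292), and in marginal zone-like (0.197) and plasma cell-like cells (0.251) without double-knockout library 2. Germinal center-like cells gained it without single-knockout library 1 (0.00128), single-knockout library 2 (0.0461) or double-knockout library 2 (0.0124). Heavy chain RNA released by other cells can enter any droplet, so the values of every class can include it.

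**Figure D2:**
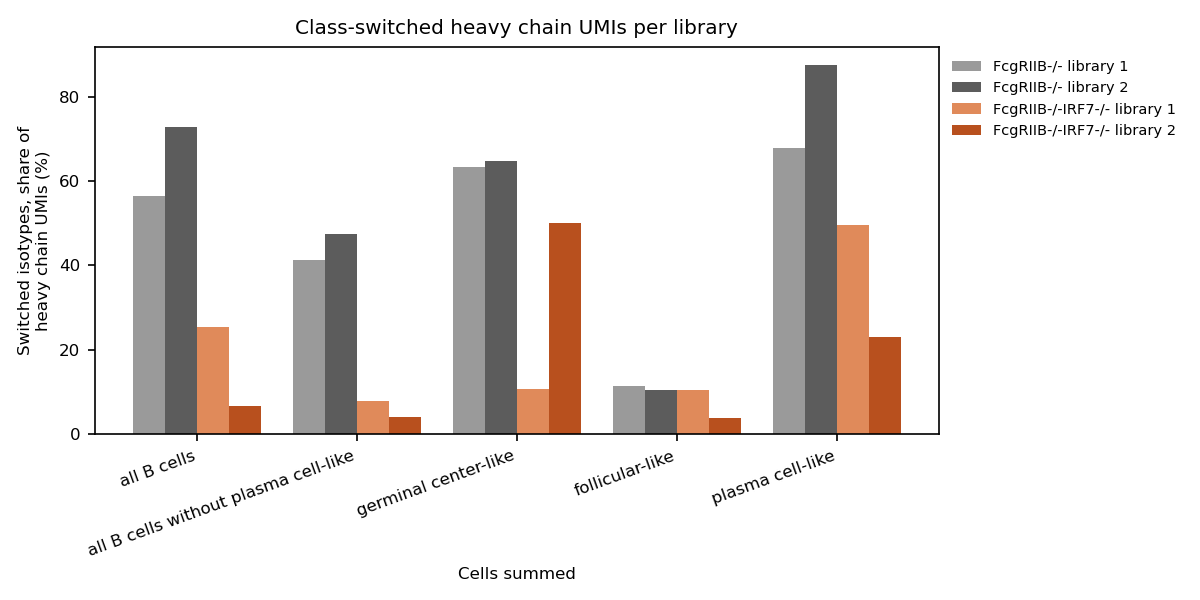
Share of heavy chain constant region UMIs from switched isotypes (vertical axis, percent) in all B cells, in all B cells without plasma cell-like cells, and in germinal center-like, follicular-like and plasma cell-like cells, 1 bar for each of the 4 libraries. Over all B cells the single-knockout libraries are at 56.6% and 73.0% and the double-knockout libraries at 25.3% and 6.50%; in follicular-like cells they are at 11.4% and 10.4% against 10.4% and 3.82%.

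Within the classes outside the germinal center, interferon-stimulated genes were lower without IRF7. Transitional-like, follicular-like and marginal zone-like cells and clusters 4, 8, 9 and 11 had 164, 182, 175, 41, 308, 225 and 186 genes called. The interferon-stimulated list fell in each of the 7, with median log2 fold changes from -0.90 in cluster 4 to -1.56 in cluster 8. Of the measured members, 19 of 31 were lower in transitional-like, 17 of 28 in follicular-like and 30 of 36 in marginal zone-like cells, and 7 of 35, 30 of 38, 17 of 28 and 18 of 30 in clusters 4, 8, 9 and 11, with none higher. Adjusted over the list alone the lower members were 23, 22, 32, 25, 35, 21 and 21, with 1 higher in clusters 9 and 11. The camera adjusted p ran from 1.5e-35 in marginal zone-like cells to 5.2e-15 in cluster 9, and no call held with an estimated correlation (adjusted p = 0.514 to 0.603 with an estimated correlation). The fry test called the list lower in 5 of the 7, all but clusters 4 and 9.

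Ifi27l2a fell in each of the 7. In transitional-like cells it went from 2140 and 2488 CPM to 143 and 127 CPM (log2 fold change -4.02, SE 0.11, edgeR adjusted p = 3.2e-19), and its log2 fold change was -3.17 in follicular-like cells, -3.17 in marginal zone-like cells, -3.90 in cluster 8, -3.38 in cluster 9, -3.15 in cluster 11 and -2.83 in cluster 4. Rtp4, an antiviral chaperone-like gene, was at 43.4 and 60.5 CPM against 0.409 and 2.82 CPM in cluster 8 (log2 fold change -5.22, SE 0.40). Ifit3, which restricts viral RNA, was at 58.4 and 34.3 CPM against 3.91 and 4.03 CPM in marginal zone-like cells, and Oasl1 fell by 4.79 in cluster 8 on the log2 scale. Slfn5 fell by 3.95 and Parp14 by 1.48 in transitional-like cells. Stat1, the transcription factor of interferon signalling, fell by 1.15 in follicular-like and 1.19 in marginal zone-like cells. Ly6a, the Sca-1 antigen, fell by 2.44 in follicular-like cells, 2.91 in cluster 9 and 3.18 in cluster 11. In cluster 4 Xaf1 was at -1.60 and the peptide transporter gene Tap1 at -0.80. Cluster 8 counts Ifi27l2a among its leading genes although the list was not used for clustering.

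MHC class I genes, many of them interferon-inducible, fell with these. The list fell in the same 7 classes and clusters, with median log2 fold changes from -0.39 in transitional-like to -0.65 in follicular-like cells (camera adjusted p from 8.3e-09 to 2.3e-06) and 6, 11, 10, 1, 10, 9 and 9 of 19 members called lower in transitional-like, follicular-like and marginal zone-like cells and clusters 4, 8, 9 and 11. Adjusted over the list alone these were 14, 14, 13, 14, 14, 12 and 12, with 1 higher in cluster 8. H2-Q7 (ENSMUSG00000060550, chromosome 17, 35439155 to 35443773) went from 351 and 335 CPM to 80.4 and 80.1 CPM in transitional-like cells (log2 fold change -2.01, SE 0.12) and fell by 2.07 in cluster 8, 1.74 in follicular-like and 0.93 in marginal zone-like cells. H2-K1 fell by 0.90 in transitional-like and 0.83 in follicular-like cells. H2-Q7 has near-identical neighbours between which reads can be split, so its own share is uncertain. With an estimated correlation no call held (adjusted p = 0.514 to 0.680 with an estimated correlation). Single-gene counts in these classes depended on single libraries. Without double-knockout library 1, 0 genes passed in marginal zone-like cells (12 without double-knockout library 2) and 1 in cluster 4 (10 without double-knockout library 2), and with 1 library left out they ranged from 77 to 367 in transitional-like, 74 to 617 in follicular-like, 155 to 552 in cluster 8, 91 to 664 in cluster 9 and 41 to 341 in cluster 11.

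**Figure D3:**
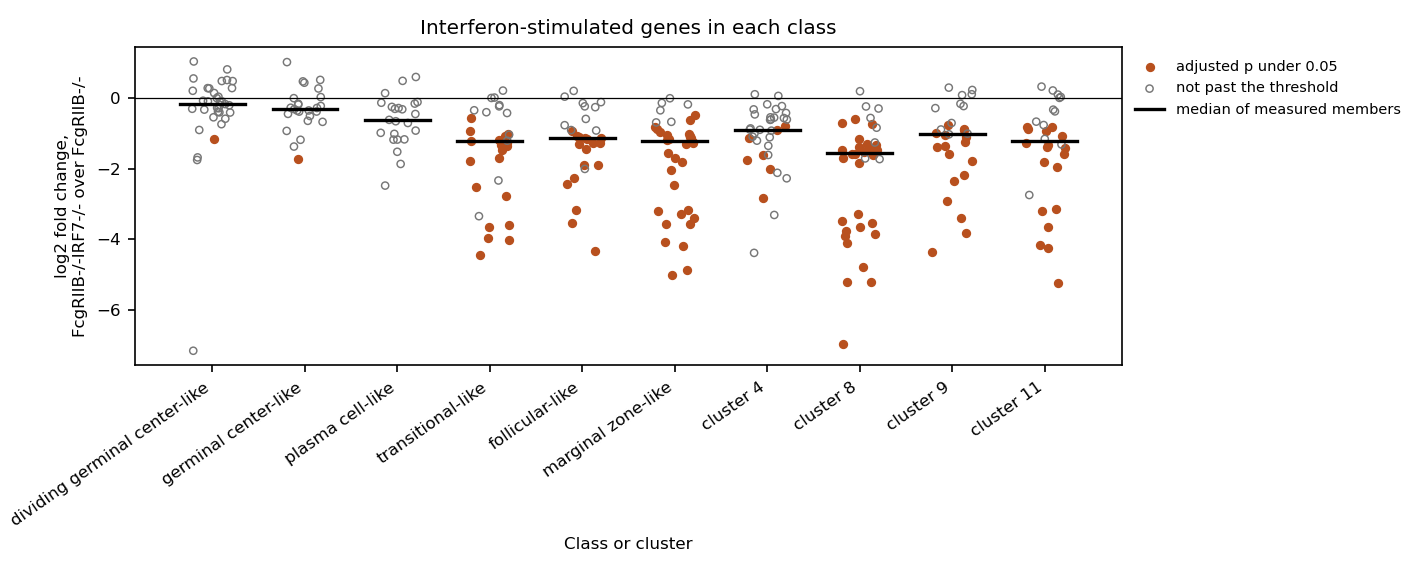
Log2 fold changes (double-knockout over single-knockout, vertical axis) of the measured interferon-stimulated genes in each class or cluster, 1 point per gene, filled where the adjusted p is under 0.05, with a bar at the median of the measured members. Medians are -0.90 to -1.56 in the 7 classes and clusters outside the germinal center and plasma cell classes, -0.31 in germinal center-like and -0.17 in dividing germinal center-like cells.

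Genes of dividing and germinal center cells were also lower in these non-germinal-center classes. The cell cycle list fell in all 7, with medians from -0.42 in cluster 4 to -1.67 in cluster 8 (camera adjusted p from 6.3e-26 to 2.1e-05). Called lower were 14 of 30 members in transitional-like, 10 of 21 in follicular-like and 14 of 28 in marginal zone-like cells and 0 of 35, 19 of 31, 7 of 29 and 5 of 27 in clusters 4, 8, 9 and 11. Adjusted over the list alone these were 21, 13, 17, 10, 25, 11 and 7, with 1 higher in cluster 4. Stmn1, a microtubule regulator of dividing cells, was at 97.9 and 103 CPM against 18.5 and 13.6 CPM in transitional-like cells, and at -2.36 in cluster 8, -2.86 in marginal zone-like and -1.62 in follicular-like cells. In transitional-like cells it turned to 0.12 without a call after free RNA was subtracted. Pclaf, a replication factor, fell by 3.90 in transitional-like and 3.18 in marginal zone-like cells, and Top2a by 3.64 in cluster 8. The germinal center list fell in transitional-like, follicular-like and marginal zone-like cells and cluster 8 (medians -0.40, -0.22, -1.01 and -0.85), with 7, 4, 7 and 9 members called lower and 7, 4, 9 and 12 lower and 1 higher in each adjusted over the list alone. Basp1 was at -3.35 in transitional-like cells and -3.86 in cluster 8, and Mef2b at -3.87 in transitional-like cells. The dark zone list fell in follicular-like cells, where its median was 0.01, in marginal zone-like cells (-1.59) and in clusters 4 (-0.18) and 8 (-1.34). Germinal center classes supplied 76.3% and 75.8% of B cell UMIs in single-knockout but 9.68% and 8.51% in double-knockout libraries, and after free RNA was subtracted the cell cycle list was called lower in 0 of the 7 and higher in cluster 11 (camera adjusted p = 0.00832). The germinal center medians then turned to 0.28 in transitional-like (called higher, camera adjusted p = 0.0108), 0.16 in follicular-like and 0.17 in marginal zone-like cells and 0.13 in cluster 8, and the list was called higher in clusters 4 (0.0142), 9 (0.0158) and 11 (0.0365). The markers that sized the subtraction all belong to the germinal center list, so its turn decides nothing. The dark zone list turned upward without a call in follicular-like (0.319) and marginal zone-like cells (0.890) and cluster 8 (0.176) and no longer passed in cluster 4 (0.859). Aicda and Gcsam, which helped size the subtraction, are on this list, so its turn is partly built in. At equal cells and depth the cell cycle list kept its call in all 7, with medians of -0.88 in cluster 8 and -0.75 in transitional-like cells against -1.67 and -1.64 before, the germinal center list kept its call in cluster 8 alone and the dark zone list in none. Left-out libraries ended the germinal center call in follicular-like (0.0731, without single-knockout library 1) and transitional-like cells (0.511 and 0.313, without double-knockout library 1 or 2), and the dark zone call in follicular-like cells (0.995 and 0.0761, without single-knockout library 1 or 2) and cluster 4 (0.168 and 0.442, without single-knockout or double-knockout library 2). No call held with an estimated correlation (adjusted p = 0.514 to 0.699 with an estimated correlation).

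Genes called higher and lower numbered 46 and 118 in transitional-like, 63 and 119 in follicular-like and 38 and 137 in marginal zone-like cells, and 10 and 31, 103 and 205, 78 and 147 and 60 and 126 in clusters 4, 8, 9 and 11. More rose than fell in cluster 9 with the stricter cell filter (170 and 122) and, without double-knockout library 1, in cluster 11 (176 and 165) and transitional-like cells (202 and 165). Camk2d (ENSMUSG00000053819, chromosome 3, 126596302 to 126846326), a calcium-dependent kinase subunit, rose in 9 of the 10 classes and clusters, with log2 fold changes of 1.36 in transitional-like, 1.67 in follicular-like, 1.94 in marginal zone-like, 1.86 in dividing germinal center-like and 1.76 in germinal center-like cells and 3.33, 1.37, 2.19 and 1.36 in clusters 4, 8, 9 and 11. In cluster 4 it went from 20.8 and 16.9 CPM to 186 and 206 CPM (SE 0.16, edgeR adjusted p = 3.2e-06). The follicular and quiescence list rose in 9 of the 10, all but cluster 4, with medians from 0.19 in transitional-like to 0.92 in dividing germinal center-like cells (camera adjusted p from 4.1e-10 to 0.0273; adjusted p = 0.514 to 0.696 with an estimated correlation). S1pr1 rose by 0.66 in transitional-like and 0.52 in follicular-like cells, the anti-proliferative gene Btg1 by 0.50 in marginal zone-like cells, 0.53 in cluster 9 and 0.50 in cluster 11, and Zfp36l2 by 0.68 in cluster 8. In transitional-like cells the list call was lost without single-knockout library 1 (camera adjusted p = 0.269), single-knockout library 2 (0.336) or double-knockout library 2 (0.0874). The same libraries ended it in marginal zone-like cells (0.0524, 0.0824 and 0.128). It was also lost in follicular-like cells without single-knockout library 2 (0.0530) or double-knockout library 2 (0.0909), in clusters 9 (0.218) and 11 (0.0872) without single-knockout library 2, and in plasma cell-like cells without double-knockout library 2 (0.0858), and gained in cluster 4 without double-knockout library 1 (0.0293). After free RNA was subtracted it was lost in transitional-like (0.226) and marginal zone-like cells (0.767). In cluster 9 the nucleolar genes Ncl and Npm1 fell by 0.56 and 0.48. The mitochondrial gene mt-Nd3 rose by 1.10 in transitional-like cells and 1.19 in cluster 8, beside the higher mitochondrial share of the double-knockout libraries (3.69% and 5.30% against 3.17% and 2.65%).

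The few germinal center cells of the double-knockout libraries (239 and 190 cells against 4767 and 5423) differed from those of the single-knockout libraries in Ighm and in other single genes such as Cr2 and Foxp1. Most list calls ended after free RNA was subtracted. None held with an estimated correlation, a setting that called no list in any comparison. In dividing germinal center-like cells 280 of 11518 genes passed, 183 higher and 97 lower, and in germinal center-like cells 93 of 9515, 48 higher and 45 lower. With free RNA subtracted 86 passed in the dividing class, 79 of them among the 280, and 28 in the other, 16 of them among the 93, and at equal cells and depth 95 and 24 passed. More fell than rose without double-knockout library 1 (330 higher and 559 lower in the dividing class, 316 and 489 in the other), without double-knockout library 2 (257 and 259, 159 and 278) and with no count filter (408 and 461, 183 and 383). Ighm rose from 346 and 285 CPM to 1820 and 1489 CPM in the dividing class (log2 fold change 2.32, SE 0.14, edgeR adjusted p = 2.3e-05) and by 2.12 in the other. Ighg2c fell by 2.70 and Ighg2b by 1.23 in the dividing class, while Ighg1 held 15.7% and 15.4% of heavy chain UMIs there against 3.69% and 19.6%, and 21.9% and 19.6% against 3.64% and 36.7% in the germinal center-like class, with double-knockout library 2 the highest in both. The complement receptor Cr2 rose by 2.28 and 1.87 and the transcription factor Foxp1 by 0.97 and 0.88 in the dividing and the germinal center-like class. Gcsam fell by 0.76 and 1.25, Ifi27l2a by 1.15 and 1.74, and Ifi27 by 2.37 and 1.81. In the dividing class Plac8, a leading gene of cluster 11, rose from 5.63 and 6.03 CPM to 109 and 104 CPM, S100a10 rose by 3.77, Klf2 by 2.09 and the survival gene Bcl2a1b, whose near-identical copies can share its reads, by 1.34, while Rflna fell by 1.87 and Tox2 by 1.61. In the germinal center-like class Wnt10a rose by 3.88, Cd55 by 1.75 and Il4i1 by 0.99, and Ldha, Pkm and Gapdh of glycolysis fell by 0.87, 0.88 and 0.61.

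In the dividing class the follicular and quiescence, marginal zone, memory, B1 and NF-kB lists rose, with 9 of 18, 8 of 15, 7 of 15, 2 of 11 and 4 of 24 members called higher and 14, 10, 8, 5 and 5 adjusted over the list alone, and the interferon-stimulated, dark zone, class-switched and oxidative phosphorylation lists fell. In the germinal center-like class the follicular and quiescence, marginal zone, NF-kB, light zone and B cell receptor lists rose, and the interferon-stimulated, cell cycle, Myc and glycolysis and oxidative phosphorylation lists fell. In the germinal center-like class 3 of 34 cell cycle members were lower, among them Stmn1 at -0.72 and Pclaf at -1.11, and after free RNA was subtracted Stmn1 was at 0.11 without a call, while Pclaf was left with 0 UMIs in both single-knockout libraries and 8 and 29 in the double-knockout libraries, so it gives no fold change there. The interferon-stimulated list had 1 of 35 members called lower in the dividing and 1 of 25 in the germinal center-like class (4 and 2 adjusted over the list alone), with medians of -0.17 and -0.31 (camera adjusted p = 0.0357 and 0.0217). No list call held with an estimated correlation (adjusted p = 0.514 to 0.704 with an estimated correlation), and the interferon call in the dividing class was lost without single-knockout library 1 (camera adjusted p = 0.258) or double-knockout library 2 (0.302). Leaving out 1 library gave 145 to 889 calls in the dividing and 52 to 805 in the germinal center-like class.

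Free RNA subtraction ended most of these list calls, but it was sized on follicular markers that all belong to the follicular and quiescence list. The loss of that list's call is therefore partly built in and decides nothing. In the dividing class the follicular and quiescence (camera adjusted p = 0.360), memory (0.590), B1 (0.226), NF-kB (0.0997), interferon-stimulated (0.0591), dark zone (0.254) and class-switched lists (0.269) no longer passed, and the marginal zone (0.008) and oxidative phosphorylation lists (0.0203) did. In the germinal center-like class the follicular and quiescence (0.624), marginal zone (0.498), light zone (0.0997), B cell receptor (0.572) and oxidative phosphorylation lists (0.140) no longer passed, the cell cycle list was called higher (8.9e-05), and the NF-kB (0.0106), Myc and glycolysis (0.0156) and interferon-stimulated lists (0.00728) kept their calls. At equal cells and depth the interferon-stimulated list lost its call in the dividing (0.752) and the germinal center-like class (0.507), the dark zone (0.830) and B1 lists (0.752) in the dividing class, and the light zone (0.0902) and oxidative phosphorylation lists (0.0501) in the germinal center-like class. The fry test called the memory and marginal zone lists in the dividing class and the follicular and quiescence and oxidative phosphorylation lists in the germinal center-like class, and no other list in either. Left-out libraries also ended calls. In the dividing class the B1 list was lost without double-knockout library 1 (0.790), the NF-kB (0.152) and oxidative phosphorylation lists (0.0972) without double-knockout library 2, and the dark zone list without single-knockout library 2 (0.161) or double-knockout library 1 (0.271) or 2 (0.127). In the germinal center-like class the marginal zone (0.254), Myc and glycolysis (0.242), light zone (0.0736) and B cell receptor lists (0.170) were lost without double-knockout library 1, the last 2 also without double-knockout library 2 (0.264 and 0.0596), and the light zone list without single-knockout library 1 (0.104).

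In plasma cell-like cells no gene passed the edgeR test among 7448, with 437 at an unadjusted p under 0.05 and 26 called by DESeq2. The class held 160, 269, 79 and 21 cells per library. The smallest p values belonged to genes named above as well. Camk2d was at 8.75 and 4.87 CPM against 53.6 and 57.8 CPM (edgeR adjusted p = 0.117), Ifi27 at 52.0 and 54.8 CPM against 6.62 and 7.22 CPM (edgeR adjusted p = 0.117), and Ighg1 at 4245 and 7826 CPM against 343 and 632 CPM (edgeR adjusted p = 0.155). Irf7 was at 20.8 and 18.3 CPM against 0.662 and 0 CPM (edgeR adjusted p = 0.172). The interferon-stimulated list fell by camera (median -0.62, adjusted p = 0.00189; adjusted p = 0.525 with an estimated correlation), with 0 of 23 members called and 1 lower adjusted over the list alone. It lost its call without double-knockout library 1 (camera adjusted p = 0.563) and at equal cells and depth (0.0845). Camera also called the germinal center (median -0.49, adjusted p = 0.00365), dark zone (-0.60, 0.0437), cell cycle (-0.40, 1.4e-05), oxidative phosphorylation (-0.22, 0.00479) and class-switched lists (-0.24, 0.0155) lower and the memory (0.47, 0.0140), follicular and quiescence (0.92, 7.4e-05), marginal zone (0.49, 6.7e-05) and B1 lists (0.30, 0.0346) higher. With 1 library left out each of these lost its call: the germinal center (0.236) and memory lists (0.124) without double-knockout library 1, the dark zone (0.0559), cell cycle (0.0559, reversed), class-switched (0.251), follicular and quiescence (0.0858) and marginal zone lists (0.0732) without double-knockout library 2, oxidative phosphorylation without single-knockout (0.130) or double-knockout library 2 (0.427), and B1 without either of these (0.473 and 0.0782) or double-knockout library 1 (0.320). None held with an estimated correlation (adjusted p = 0.566 to 0.739 with an estimated correlation), and fry called no list in this class. Without that library 506 genes passed.

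The genotype effect was compared directly between germinal center-like and follicular-like cells. Of 8263 genes tested for the interaction, 77 passed, 68 with a higher effect in germinal center-like cells and 9 with a lower one, and 712 had an unadjusted p under 0.05. Ly6a was at -0.45 in germinal center-like cells, without a call (edgeR adjusted p = 0.179), and at -2.44 in follicular-like cells. The difference was 1.99 (SE 0.15, edgeR adjusted p = 9.3e-09). The MHC class I genes H2-Q7 and H2-K1 differed by 1.67 and 0.95, and Ighm by 1.79, having risen by 2.12 in germinal center-like cells with 0.31 in follicular-like cells. The interferon-stimulated list differed between the classes (median difference 0.63, camera adjusted p = 3.5e-07; adjusted p = 0.228 with an estimated correlation). Without single-knockout library 1, 15 genes passed, and without single-knockout library 2, 31. With free RNA subtracted 19 passed, 13 of them among the 77.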

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

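Whether the loss of IRF7 acts alike in germinal center-like and follicular-like cells was tested with an interaction term, and 77 genes differed. The effect in germinal center-like minus that in follicular-like cells was 1.99 for Ly6a, 1.67 for H2-Q7, 1.79 for Ighm, 1.17 for Cybb, 0.55 for Malat1, 0.83 for Iglc2, 0.95 for H2-K1, 3.14 for Jchain, 0.79 for Hmgb2 and 1.47 for Ifi27l2a on the log2 scale. Tested on the same term, a choice made after the data were seen, the interferon-stimulated list differed with a median of 0.63 (adjusted p = 0.228 with an estimated correlation). Other lists differed too, among them marginal zone (median 1.22), germinal center (1.12), dark zone (1.07), light zone (0.71), cell cycle (0.59), NF-kB (0.59) and MHC class I (0.38), and none of these passed with an estimated correlation (adjusted p = 0.228 to 0.367 with an estimated correlation). H2-Q7 shares reads with near-identical neighbours, and the immunoglobulin genes and Jchain are abundant in free RNA. After free RNA was subtracted 19 genes differed, 13 of them among the 77, and of the 10 genes named here Malat1, Iglc2, Jchain and Hmgb2 no longer passed.

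The lower interferon-stimulated genes outside the germinal center classes were weighed against technical causes, with each prediction written before its test. Free RNA from germinal center cells would end the calls, yet the list stayed lower in 7 of 7 classes and clusters after it was subtracted, by the preset correlation of 0.01 (before subtraction adjusted p = 0.514 to 0.603 with an estimated correlation, no call). A strain or passenger segment around a deleted gene would put the genes near Irf7 or Fcgr2b. Of the lower members 0% lay within 20 Mb of either, but this test read only members of the fixed list. Genes off the list within 20 Mb of Irf7 or of Fcgr2b were called both ways. Among those near Irf7, Sbk1 was higher in 5 of 9 classes and clusters tested, and Rgs10 and Mki67 were lower in 3 of 10. Among those near Fcgr2b, Ifi214, Ifi208 and Ifi209 were lower in 7 of 10, 5 of 6 and 3 of 10, and Fcrla and Gm2000 higher in 3 of 10. A difference in depth between the groups' cells would end the calls at equal cells and depth, where the list was still lower in 7 of 7. Free RNA and depth are excluded as the whole cause at the preset correlation. A segment is not excluded, because the test read no genes off the list and some of those near the deleted genes were called. The deletion of Irf7 remains open and untested.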

How the results depend on the processing

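The alternatives named equal cells and depth, free RNA subtracted, genes called within any class left out, wider classes, share outside the germinal center, crossed pairing, limma with class makeup as sampled and lists on the interaction were chosen after the data were seen, and plasma cell-like cells were dropped from the free-RNA alternative after its marker share of over 75% and its calls had been seen. A library left alone in its group was assumed to vary like the other group. Of 2122 values of named genes under alternatives, 1936 kept direction and side of the threshold, 149 lost their call, 28 gained one and 9 reversed. Of 2650 for lists, 2320 stayed, 253 lost, 53 gained and 24 reversed. Of 109 class shares 98 stayed, 7 lost and 4 gained, of 80 interaction genes 73 stayed and 7 lost, of 223 counts and values that answer a comparison 125 stayed and 98 moved, and of 48 other values 45 stayed, 2 moved and 1 reversed. Unless a cause is given, the cause was not tested.

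Gene counts moved as follows. Equal class makeup gave 146 in all B cells. DESeq2 gave 36 in cluster 11, 95 in cluster 8, 61 in cluster 9, 33 in follicular-like, 93 in marginal zone-like, 26 in plasma cell-like and 99 in transitional-like cells. Equal cells and depth, which tests fewer cells and UMIs, gave 46 in cluster 11, 87 in cluster 4, 104 in cluster 8, 22 in cluster 9, 95 in dividing germinal center-like, 24 in germinal center-like, 4 in plasma cell-like and 15 in transitional-like cells, with 57 lists called within classes. No count filter gave 17 in cluster 4, 869 in dividing germinal center-like, 295 in follicular-like, 566 in germinal center-like, 322 in marginal zone-like, 165 in plasma cell-like and 251 in transitional-like cells. Doublets kept gave 244 in cluster 4, 98 in cluster 9, 282 in marginal zone-like and 687 in transitional-like cells. The stricter cell filter gave 76 in cluster 4, 120 in cluster 8 and 252 in transitional-like cells. Leiden resolution 2 gave 97 in cluster 4, 112 in follicular-like, 165 in germinal center-like and 1 in plasma cell-like cells, and resolution 0.5 gave 88 in cluster 9, 773 in dividing germinal center-like and 1118 in transitional-like cells. Free RNA subtracted gave 74 in cluster 4, 189 in cluster 8, 81 in cluster 9, 86 in dividing germinal center-like and 28 in germinal center-like cells, 41 lists within classes and 19 interaction genes. Wider classes gave 366 interaction genes, and an estimated correlation 0 lists in all B cells and 0 within classes.

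The difference in germinal center share was -54.8 points with doublets kept, -54.0 with the stricter filter, -52.5 at resolution 2, -53.4 at resolution 0.5, -37.8 with called genes left out of the clustering, where 2 share calls were left, and -53.4 with genes called within any class left out. Thinned to equal UMIs per cell, Irf7 was at -4.42 and Fcgr2b at 1.35.

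The replicate numbers in the titles were also used as a block, although the labels share only a number. The block gave 188 in cluster 4, 94 in follicular-like, 52 in germinal center-like, 102 in marginal zone-like and 9 in plasma cell-like cells. Among named genes it ended the calls of S1pr1 and Fcer2a in follicular-like and of mt-Nd3 and Btg1 in marginal zone-like cells and added one for Ighg1 in plasma cell-like cells. It ended the calls of the NF-kB list in all B cells (adjusted p = 0.0714), the dark zone list in dividing germinal center-like (0.0525), oxidative phosphorylation in marginal zone-like (0.0715), B1 in plasma cell-like (0.0509) and follicular and quiescence in transitional-like cells (0.0668). It added the class-switched list in all B cells (0.0312) and in germinal center-like cells (0.0406), the germinal center list in cluster 4 (0.0190) and the dark zone list in transitional-like cells (0.0373). No other call changed with it, and no other count moved by more than 1.5 times. Crossed pairing gave 870 in cluster 4 and 11 in plasma cell-like cells.

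With 1 library left out, called genes ranged from 4688 to 8884 in all B cells, 41 to 341 in cluster 11, 1 to 63 in cluster 4, 155 to 552 in cluster 8, 91 to 664 in cluster 9, 145 to 889 in dividing germinal center-like, 74 to 617 in follicular-like, 52 to 805 in germinal center-like, 0 to 155 in marginal zone-like, 11 to 506 in plasma cell-like and 77 to 367 in transitional-like cells. Lists ranged from 13 to 15 in all B cells and 69 to 83 within classes, interaction genes from 15 to 104 and share calls from 4 to 7. The germinal center difference ran from -53.1 to -52.9 points, the switched share difference from -58.3 to -39.5, Irf7 from -4.80 to -4.57 and Fcgr2b from 1.85 to 1.91.

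At equal class makeup Sox4 reversed to -0.0490, Ddx58 to -0.28, Samd9l to -0.0579, Kif11 to 0.0408, Aurkb to 0.0397 and Mndal to -0.23. With free RNA subtracted Stmn1 reversed to 0.11 in germinal center-like and to 0.12 in transitional-like cells. The fit gave 9.98 for Pclaf in germinal center-like cells, but the subtraction had left 0 UMIs in both single-knockout libraries there, so this value is no fold change and no reversal is read from it. With 1 library left out the difference in Ighg3 share ran from -11.3 points without single-knockout library 1 to 0.536 without single-knockout library 2, where it reversed.

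Lists that reversed are given with their adjusted p. With free RNA subtracted, the germinal center list reversed in clusters 11 (0.0365), 4 (0.0142), 8 (0.624) and 9 (0.0158) and in follicular-like (0.419), marginal zone-like (0.767) and transitional-like cells (0.0108). The cell cycle list reversed in clusters 11 (0.00832), 4 (0.943), 8 (0.0566) and 9 (0.959) and in germinal center-like (8.9e-05), marginal zone-like (0.976) and transitional-like cells (0.359). The marginal zone list reversed in cluster 4 (0.000434), the dark zone list in cluster 8 (0.176), follicular-like (0.319) and marginal zone-like cells (0.890), and the class-switched list in marginal zone-like cells (0.859). At equal cells and depth the dark zone list reversed in follicular-like (0.535) and the germinal center list in transitional-like cells (0.926). With 1 library left out, the adjusted p ran from 0.00183 to 0.995 for the dark zone list in follicular-like cells, which reversed at 0.995, without single-knockout library 1. In plasma cell-like cells it ran from 0.00181 to 0.676 for the light zone list and from 1.4e-18 to 0.0559 for the cell cycle list, which reversed without double-knockout library 2, at 0.00181 and 0.0559.

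The plasma cell-like class held 21 cells in 1 library and had a common dispersion of 0.0429, and on simulated data 4.12% of 2-fold changes were called there. Depth and spread were not separated as causes.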

Other observations

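A neighbourhood on chromosome 12, picked after the calls were seen, held several of the lower genes. Of 15 genes tested within 1 Mb of Ifi27l2a, itself counted, 5 were lower in any class, Serpina3f in 1 alone, and 0 higher. The share of all genes lower in any class was not set beside this count. Ifi27l2a was lower in 9 of the 10 classes and clusters, Ifi27 in 8, Serpina3g in 7 and Ddx24 in 6. No explanation was tested for this grouping.

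The cell cycle list was lower in 7 and the germinal center list in 4 of the 7 classes and clusters outside the germinal center, none with an estimated correlation (adjusted p = 0.514 to 0.699 with an estimated correlation), and free RNA from germinal center cells was predicted to end this. The first 3 predictions were written before their tests, and those for 4 classes after. After subtraction the cell cycle list was lower in 0 of 7 classes and clusters, as predicted for free RNA. It was called higher in cluster 11 (camera adjusted p = 0.00832), so the subtraction may take off too much. Germinal center genes then turned higher in 4 of the 7, but the markers that sized the subtraction belong to that list. Doublets of a germinal center cell left in the other classes, and fewer dividing cells inside those classes, could not be told apart from it: 24.8% of proliferating marker UMIs were in cells with 5 or more, and 0 calls were left after subtraction. In cluster 8 and the follicular-like, transitional-like and marginal zone-like classes that share was 3.72%, so cells with 5 or more were not the main source there. Doublets and dividing cells with fewer than 5 are not covered by this. Cell cycle genes went into the clustering, so cells with many of these UMIs may have been placed in the dividing class. Neither cause is therefore excluded there, and an effect of the Irf7 deletion was not tested.

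Besides Irf7, 11 genes changed the same way in at least 8 of the 10 classes and clusters, a set defined after the calls were seen. The tests of a passenger segment, of the parts of the set and of double-knockout against single-knockout library 1 were also chosen after. Those of library 2 and of free RNA over the set were chosen before. Of the 11, 0% lay within 20 Mb of a deleted gene. This does not exclude a passenger segment, because the cutoff of 8 left out Ifi214, within 20 Mb of Fcgr2b and lower in 7 of 10. In 90.9% double-knockout library 2, with the higher mitochondrial share, lay further from the single-knockout mean than library 1. This met the prediction written beforehand for RNA quality as a cause. The mitochondrial share of double-knockout library 1 was close to that of single-knockout library 1. The change of double-knockout library 1 from that library was still at least 0.599 of the change of library 2 in each of the 11. Called genes nearly always had both double-knockout libraries apart from the single-knockout ones. A large change in library 1 was thus largely built into the choice of the 11. This later test therefore does not exclude RNA quality, as read by that share, as a cause. After free RNA was subtracted 45.5% kept their call in at least 7 classes. Camk2d, Gm10076, Gm43305, Ifi27 and Ifi27l2a kept it in at least 7 of 9. They were grouped after this was seen, and single markers sized the subtraction unlike, so free RNA is not excluded for them. Anxa2, Hist1h1b, Ighg2c and Mef2b kept it in at most 1 of 9. For these, free RNA cannot be told apart from too few counts left (tested in 2 to 5 of 9). Ebf1 and Gm49980 lay in between, and the deletion of Irf7 was untested as a cause.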
